A study of Homo sapiens with 4 samples.

How the data were processed

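RNA sequencing was measured in 4 libraries of human 8-cell-like cells (8CLC, cells derived from the H1 embryonic stem cell line that express genes of the 8-cell embryo). Per the labels, the cells were kept in mTeSR medium and transfected by endofectin with an antisense oligonucleotide (ASO, a short synthetic strand that binds an RNA and lowers its level) against LINE-1 or with a control ASO. The cells were collected 24 h later, total RNA was extracted with TRIZOL, and libraries were made with the Vazyme TD503 and TD202 kits. Each ASO has 2 libraries, and the labels do not say whether these come from separately transfected cultures, nor how RNA was enriched or whether the reads keep their strand.

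The authors deposited a table of raw counts per gene and per repeat subfamily, with 61822 rows, of which 60642 are genes and 1180 are repeats. They also deposited TPM for the same libraries, which are values scaled by length and depth, and per the file header each column holds a single library. The deposited TPM are scaled over genes and repeats together, so a fall of repeat reads moves every gene's TPM. The row names of the tables differ in 1 row. The submitters' processing notes name FastQC 0.11.9, cutadapt 4.1, STAR 2.7.10a, featureCounts 2.0.1 and edgeR 3.30.3 with the builds GRCh38 and hg38, without their roles or settings. The gene annotation, the strand setting and the rule for reads that match several places are not given in the sources used here. Genes and repeat subfamilies with near-identical copies, and genes that overlap on opposite strands, are therefore uncertain. A gene length was recovered from the ratio of count to TPM, and positions come from GENCODE v29, in which 55385 genes (91.3%) matched a single gene by symbol. For 71.5% of these the recovered length equals the v29 union exon length within 0.1%.

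Counts were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood fit and test (glmQLFit, glmQLFTest), the filterByExpr filter, and library sizes and TMM factors from gene rows only. Genes and repeats shared 1 fit, the LINE-1 total was tested in a separate fit, and p-values were adjusted by the Benjamini-Hochberg method separately over genes and over repeats, with a threshold of 0.05. All adjusted p-values given for genes and repeats are two-sided and from edgeR unless another tool is named. Log2 fold changes are LINE-1 ASO minus control ASO, and each standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Levels of named genes and repeats are CPM relative to the library's gene counts, scaled by the TMM factors, and are given with their SD. CPM per kilobase are relative to gene counts without the TMM factors. The p-values measure only the spread between these samples, which may be technical.

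Gene lists (28) and repeat lists (15) were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, against all other tested genes or repeats, and adjusted over the lists. A list needed at least 3 tested members. The gene lists cover 8-cell genes, naive, primed and core pluripotency, markers of trophectoderm, endoderm, mesoderm, neuroectoderm, amnion and mesenchyme, and the interferon, p53, integrated stress (ATF4 and its targets), heat shock with unfolded protein, and immediate early responses. They also cover ribosomal proteins, ribosome biogenesis, LINE-1 silencing factors, ZNF zinc finger genes, histones, mitochondrial genes, nuclear respiratory chain genes, glycolysis, cholesterol synthesis, S phase, G2/M phase, splicing, and nuclear and small nucleolar RNA host transcripts. The repeat lists cover youngest LINE-1, older L1PA, L1PB, L1M, L2 with L3 and CR1, Alu, SVA, HERVH with LTR7, HERVK with LTR5, MLT2A with HERVL, MaLR, LTR12, satellites, DNA transposons and MIR. For each list the members past the threshold were counted over all genes tested and, with the p-values adjusted over the list alone, a second time. Lists written as symbol prefixes leave out pseudogenes; this was set in advance for ribosomal proteins and extended to the other prefixes after the data were seen. The medians of 6 gene lists were also set against 10000 random lists matched on gene length and mean expression. The respiratory chain list, made by prefix, also holds assembly factors and antisense transcripts of its genes.

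The text names L1HS, L1PA2 to L1PA8 and the LINE-1 total, and the 10 genes with the largest rise and the 10 with the largest fall. Both sets had to pass the threshold, reach a mean of 5 CPM over the 4 libraries and have both LINE-1 ASO libraries on the same side of both control libraries; clone names, Y-linked genes and XIST were left out. It also names up to 4 members of each gene list with the smallest p, the 5 repeats with the smallest p in each direction, and ZSCAN4, TPRX1, DUXA, LEUTX, KLF17, POU5F1, SOX2 and NANOG. Further members are named to complete a count of 5 or fewer or where a group is singled out; these were chosen after their values were seen. The design, tests, lists and naming rule, and most of the other settings below, were fixed before the data were examined.

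The other settings tried were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, library size from all rows, no filter, a filter of at least 1 CPM in 2 libraries, the replicate number as a block, and leaving out each library in turn. Further ones were limma-trend on log2(TPM + 1) and on log2(TPM + 0.1), a mean TPM of at least 1, an absolute log2 fold change of at least 1, adjustment over genes and repeats together, camera with an estimated correlation, and fry. Added after the data were seen were fits on genes at least 10 times the background, on protein-coding genes only, and on counts from which a background had been subtracted. The background was measured in 661 genes of 7 families that are silent outside specialised tissues (olfactory and bitter taste receptors, keratin-associated proteins, beta-defensins, late cornified envelope proteins, and immunoglobulin and T cell receptor V segments). The density subtracted was either the median over these genes or the pooled density of the 369 that lie over 100 kb from any gene with at least 1 CPM in the LINE-1 ASO libraries. A gene or repeat that lost over 80% of its control counts by the subtraction was given no value.

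Tested on simulated data with 26589 genes tested, edgeR recovered 38.8% of 67 genes changed 1.25-fold, 65.7% of 67 changed 1.5-fold and 95.5% of 66 changed 2-fold, with 4 false calls among 137. DESeq2 recovered 17.9%, 40.3% and 80.3%, limma-voom 37.3%, 65.7% and 95.5%, and limma-trend on log2(TPM + 1) 0%, 0% and 10.6%. The simulation changed only these genes and held no background difference between groups, while 16206 of 27634 genes changed in the data. These rates therefore need not carry over to the data. When a list of 30 genes was raised 1.25-fold, camera with the preset correlation found it and no other of 28 lists, while camera with an estimated correlation (adjusted p = 0.0514) and fry (adjusted p = 0.0874) missed it. The simulated genes varied independently of each other, a setting that favours a small preset correlation. This result does not carry over to lists whose genes vary together. Other tools were the R package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No file or column of values per sample was left out.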

Results

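The data are RNA sequencing counts of genes and repeat subfamilies in 4 libraries of human 8-cell-like cells made from the H1 embryonic stem cell line, 24 h after transfection. A control ASO and an ASO against LINE-1 have 2 libraries each. LINE-1 is a retrotransposon family that makes up a large part of the human genome and is transcribed in the early embryo. The libraries held 20780113 and 27859351 counts in the control ASO group and 20044970 and 30079285 in the LINE-1 ASO group. Genes took 13312976 and 17813071 of the control counts and 16448818 and 24581838 of the LINE-1 ASO counts. Repeats took 35.9% and 36.1% of the counts in the control libraries and 17.9% and 18.3% in the LINE-1 ASO libraries. The number of genes with at least 1 count was 46561 and 48339 in the control libraries against 36338 and 38423 in the LINE-1 ASO libraries. The single comparison the design gives, LINE-1 ASO against control ASO, asks which transcripts differ when LINE-1 RNA is targeted.

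Counts on LINE-1, the target, were lower in both LINE-1 ASO libraries than in both control libraries. How much of this is LINE-1 RNA is uncertain, since genes silent in most tissues fell by like amounts per kilobase (below). The LINE-1 total fell 3.33-fold, from 140500 ± 776 to 42210 ± 437 CPM (SD, n = 2 in each group), a log2 fold change of -1.74 ± 0.03 (SE; edgeR adjusted p = 3.6e-20). L1HS, the youngest human-specific subfamily and the one with members able to move, fell 2.69-fold, from 454 ± 6.28 to 169 ± 3.71 CPM (log2 fold change -1.43 ± 0.04; edgeR adjusted p = 2.40e-16). The primate subfamilies L1PA2, L1PA3 and L1PA4 fell by 1.47, 1.61 and 1.69 on the log2 scale. L1PA5 to L1PA8 had log2 fold changes between -1.90 (L1PA5) and -1.62 (L1PA6). All 127 LINE-1 subfamilies tested fell, with log2 fold changes from -3.24 to -0.30 and a median of -1.81.

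Repeats outside LINE-1 fell as well: 1001 of 1022 tested were lower and 4 were higher, with a median log2 fold change of -1.51. Over all repeats, 1128 of 1149 tested fell, 4 rose and 17 did not pass the threshold in edgeR. The 5 repeats with the smallest p were older mammalian LINE-1 subfamilies: L1ME2 (log2 fold change -2.18), L1MA9 (-2.17), L1MC3 (-2.19), L1ME1 (-2.03) and L1M1 (-2.16), each with an edgeR adjusted p of 4.10e-18. The largest rise past the threshold was X5B_LINE, from 30.5 ± 0.0405 to 36.9 ± 0.574 CPM (SD, n = 2; log2 fold change 0.28 ± 0.06; edgeR adjusted p = 5.38e-04). MER61A (0.16, edgeR adjusted p = 8.65e-03), UCON80_AMi (0.14, adjusted p = 0.0158) and LTR6A (0.11, adjusted p = 7.10e-03) also rose. Each of these calls ended under upper-quartile scaling, where LTR6A stood at -0.02, and without control replicate 2 (adjusted p = 0.0656, 0.0791 and 0.126). That of MER61A ended also without control replicate 1 (adjusted p = 0.0669), and those of MER61A and UCON80_AMi without LINE-1 ASO replicate 2 (adjusted p = 0.144 and 0.0552). HERV-Fc1-int had 0.21 without passing (adjusted p = 0.105). It passed with no filter (0.29, adjusted p = 0.0300) and with the median or far background subtracted (1.06 and 0.98, adjusted p = 9.05e-06 and 1.40e-05). HERVH-int, the body of an endogenous retrovirus abundant in human pluripotent cells, chosen after its values were seen, was at 13620 ± 0.581 CPM in the control and 13910 ± 703 CPM in the LINE-1 ASO libraries (SD, n = 2; log2 fold change 0.03 ± 0.03; edgeR adjusted p = 0.388).

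Genes of families that are silent outside specialised tissues fell per kilobase by amounts like those of the repeats. The 661 such genes together had 0.311 ± 0.00567 CPM per kb in the control libraries and 0.0815 ± 0.00133 in the LINE-1 ASO libraries (SD, n = 2), a 3.82-fold difference and a loss of 0.230 CPM per kb. They include OR5AU1, the largest fall named below (16.7 to 0.273 CPM), which adds to this pooled loss. The LINE-1 total went from 0.277 to 0.0772 CPM per kb, a loss of 0.199, and the 4 youngest LINE-1 subfamilies from 0.182 to 0.0558, a loss of 0.126. Olfactory receptor genes, which encode odour sensors of the nose, went from 0.266 to 0.0509 CPM per kb, and T cell receptor V segments, expressed in lymphocytes, from 0.266 to 0.0927. Of the silent genes, 24.7% and 13.9% had 0 counts in the control libraries against 76.6% and 69.7% in the LINE-1 ASO libraries. The median density of these genes was 0.155 and 0.151 CPM per kb in the control libraries and 0 in both LINE-1 ASO libraries. The pooled density of those far from expressed genes was 0.145 and 0.151 against 0.00828 and 0.00749. Subtracting either therefore takes counts only or almost only from the control libraries, and the values after it depend on this. With the median density of the silent genes subtracted, the fall of the LINE-1 total was -0.68 (edgeR adjusted p = 6.42e-12), and with the density of those far from expressed genes it was -0.89. The pooled density of all 661 genes was higher and predicts 112% and 113% of the LINE-1 counts in the control libraries and 107% and 104% in the LINE-1 ASO libraries, so that nothing of the LINE-1 total is left under it. The L1M subfamilies, at 0.340 and 0.0962 CPM per kb in the control and LINE-1 ASO libraries, lie above this density. The subtraction by the median removed 100% of the control counts of L1HS and 81.9%, 81.7% and 82.4% of those of L1PA2, L1PA3 and L1PA4, so these give no value under it. L1PA5 and L1PA6 then stood at -0.06 and 0.05 without passing, and with the far density L1PA2 and L1PA3 turned to 0.54 and 0.36.

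**Figure D1:**
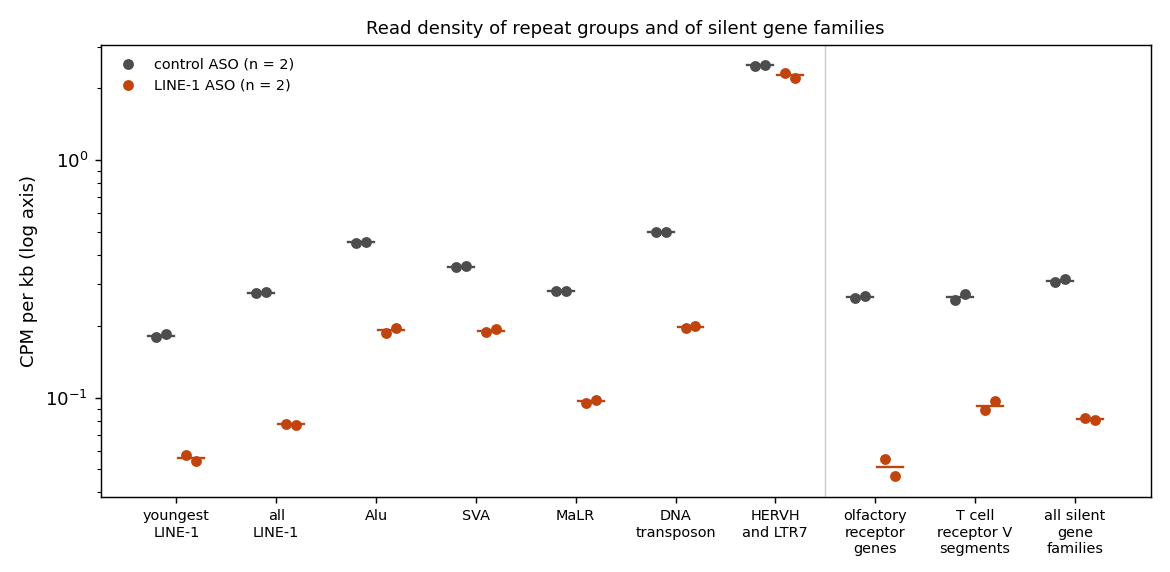
CPM per kilobase, relative to gene counts (log axis), in each of the 4 libraries for repeat groups and for gene families silent in most tissues; each point is a library and each bar the mean of 2. The LINE-1 total lies at 0.277 in the control and 0.0772 in the LINE-1 ASO libraries and all silent families at 0.311 and 0.0815, while HERVH with LTR7 lies at 2.50 and 2.28.

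By repeat list, 5 of 15 lists differed from the other repeats by camera with the preset correlation, and none did with an estimated correlation (0 lists at an unadjusted p under 0.05, and 15 by fry, which tests a list by itself). The counts adjusted over the list alone equalled those over all repeats in all 15 lists, and no list's median changed sign under another scaling. Older L1PA subfamilies (13 of 13 fell, median log2 fold change -1.90, camera adjusted p = 1.82e-08), L1PB (8 of 8, -1.98, adjusted p = 1.39e-03) and L1M (92 of 92, -1.79, adjusted p = 4.02e-26) fell by more than other repeats. Each of these had adjusted p = 0.818 with an estimated correlation. MaLR elements, a class of old retroviral repeats, fell in 81 of 81 subfamilies (median -1.59, camera adjusted p = 0.0446; adjusted p = 0.859 with an estimated correlation). That call ended without control replicate 2 (adjusted p = 0.0557) and without LINE-1 ASO replicate 1 (adjusted p = 0.0506). With the median background subtracted, the call of MaLR ended (adjusted p = 0.171) and that of L1PB reversed, to up relative to other repeats (median 0.06, adjusted p = 8.29e-03). With the far silent genes' density subtracted, both ended (adjusted p = 0.141 for L1PB and 0.518 for MaLR). With the median background subtracted, the L1M median was -0.96, and 2 of the 13 older L1PA subfamilies gave a value (median -0.01), too few for the list's test. Satellites, the tandem repeats of centromeres, fell in 10 of 11 (median -0.88). Relative to other repeats, camera placed them higher (adjusted p = 1.39e-03; adjusted p = 0.818 with an estimated correlation). The satellite that did not pass was HSAT5 (0.01).

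The youngest LINE-1 list (L1HS and L1PA2 to L1PA4) fell in 4 of 4, with a median of -1.54, but did not pass against other repeats (camera adjusted p = 0.0648). It passed, as lower, with the replicate block (adjusted p = 0.0367), without LINE-1 ASO replicate 1 (adjusted p = 0.0139) and without LINE-1 ASO replicate 2 (adjusted p = 0.0135). Alu, a short primate element, fell in 51 of 51 (median -1.17, camera adjusted p = 0.261, and 0.0477 without LINE-1 ASO replicate 2). DNA transposons fell in 120 of 120 (median -1.41, adjusted p = 0.0912, and 2.15e-06 with the median background subtracted). SVA fell in 6 of 6 (median -0.95, adjusted p = 0.814), MIR in 5 of 5 (-0.996, adjusted p = 0.665), and L2 with L3 and CR1 in 20 of 21 (-1.33, adjusted p = 0.814), all but L2-1_Crp. HERVH with its promoter repeat LTR7 fell in 5 of 6 (median -0.87, adjusted p = 0.0648), all but HERVH-int. HERVK with LTR5 fell in 19 of 20 (-1.54, adjusted p = 0.234), all but LTR5. MLT2A with HERVL, whose LTRs drive transcripts of the cleavage-stage embryo, fell in 3 of 3 (-1.39, adjusted p = 0.195) and LTR12 in 7 of 7 (-1.56, adjusted p = 0.991). With the median background subtracted, LTR12 passed as up relative to other repeats (adjusted p = 0.0427; median -0.13, 2 of 5 higher and 2 lower), and with the far density it did not (adjusted p = 0.132). For SVA, HERVH and HERVK the test's direction was up relative to other repeats while the median and mean were negative. The silent gene families lost 0.230 CPM per kb beside 0.260 for Alu, 0.165 for SVA, 0.184 for MaLR, 0.300 for DNA transposons and 0.227 for HERVH with LTR7. Satellites lost only 0.00248 CPM per kb, and single silent families lost from 0.0779 (late cornified envelope genes) to 0.776 (bitter taste receptors).

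Among genes, integrated stress response genes (30 of 35 members) and G2/M genes (28 of 32) rose, and immediate early genes such as EGR1 and FOS fell (14 of 23). Histone genes (32 of 46), mitochondrial transcripts (34 of 37) and several U1 small nuclear RNAs fell as well. The lists passed by camera with the preset correlation and not with an estimated one, while the list of 8-cell genes did not pass. In edgeR, 16206 of 27634 genes tested changed (58.6%), 7300 higher and 8906 lower, while 11428 did not pass. The median absolute log2 fold change of the changed genes was 0.65, and 264 rose and 5864 fell at least 2-fold. Of the changed genes 45% were higher under the main scaling and 28.1% under upper-quartile factors, which shift the median of all genes by -0.13 on the log2 scale. DESeq2 called 10488 genes, and 7831 of 13678 genes at least 10 times the silent-family background changed, of which 72.6% were higher.

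The largest rise was that of APBA1, a neuronal adaptor protein of synaptic vesicle release, on chromosome 9 (69427530 to 69672306, GRCh38), from 8.72 ± 1.58 to 30.7 ± 2.35 CPM (SD, n = 2; 3.49-fold; edgeR adjusted p = 2.19e-09). THRB, a thyroid hormone receptor on chromosome 3 (24117153 to 24495756), rose from 12.8 ± 1.02 to 40.0 ± 1.26 CPM (3.11-fold). ADAMTS14, a procollagen-processing protease on chromosome 10 (70672803 to 70762441), rose from 3.48 ± 0.205 to 10.9 ± 0.0635 CPM (3.10-fold). PRODH, the first enzyme of proline breakdown, rose from 23.7 ± 0.340 to 69.4 ± 2.02 CPM (2.93-fold), and F3, the tissue factor that starts blood clotting, from 11.3 ± 0.741 to 31.1 ± 0.182 CPM (2.73-fold). SORCS1, a sorting receptor, AADACL3, the cation channel TRPC6, CLIC6 and the splicing regulator RBM20 rose 3.06-fold, 2.98-fold, 2.95-fold, 2.89-fold and 2.83-fold. All 10 passed with edgeR adjusted p of 2.49e-07 or less, in both libraries of each group.

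The largest fall was that of OR5AU1, an olfactory receptor gene on chromosome 14 (21148370 to 21159060), from 16.7 ± 0.211 to 0.273 ± 0.207 CPM (SD, n = 2; log2 fold change -5.75 ± 0.23; edgeR adjusted p = 3.50e-11). MEG8, a long noncoding RNA of an imprinted locus on chromosome 14 (100894770 to 101038859), went from 18.0 ± 2.16 to 0.432 ± 0.0174 CPM (log2 fold change -5.35 ± 0.21), and the processed pseudogene IGBP1P4 from 12.1 to 0.305 CPM (-5.17). The other 7 of the 10 largest falls were U1 genes and variants, the small nuclear RNA that recognises 5' splice sites: RNVU1-25 (-5.15), RNVU1-7 (-4.52), RNVU1-29 (-4.51), RNVU1-26 (-4.50), RNVU1-27 (-4.25), RNU1-1 (-4.23) and RNVU1-6 (-4.22). RNVU1-7, the most abundant of them, on chromosome 1 (148038753 to 148038916), fell 23.0-fold, from 96.6 ± 4.04 to 4.17 ± 0.154 CPM (edgeR adjusted p = 2.06e-15). These copies are nearly identical, so which of them the reads come from is uncertain, as is the strand of reads at OR5AU1 and IGBP1P4.

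Of the 8 marker genes of the 8-cell and pluripotent states, ZSCAN4, an early target of embryonic genome activation, fell from 52.2 ± 2.94 to 41.0 ± 0.433 CPM (SD, n = 2; 1.28-fold; edgeR adjusted p = 9.43e-05). The other 8-cell transcription factors of this set did not pass: TPRX1 had a log2 fold change of -0.06 (edgeR adjusted p = 0.755), DUXA 0.07 (0.579), KLF17 0.16 (0.248) and LEUTX 0.23 (0.0568). LEUTX passed in 7 other settings, always as higher: without control replicate 1 (adjusted p = 0.0213), without LINE-1 ASO replicate 1 (0.0154), with limma-voom (0.0484), RLE factors (0.0481), library size from all rows (0.0455), no filter (6.48e-03) and the replicate block (0.0348). NANOG, a core pluripotency factor, rose from 89.5 ± 4.80 to 113 ± 1.49 CPM (1.27-fold; edgeR adjusted p = 1.36e-05). POU5F1 rose from 486 ± 18.3 to 538 ± 30.4 CPM (log2 fold change 0.15, edgeR adjusted p = 5.35e-03) and SOX2 from 187 ± 1.22 to 211 ± 4.06 CPM (0.17, adjusted p = 7.71e-04). Both calls ended under upper-quartile factors (0.02 and 0.04) and with the background subtracted (0.05 and 0.08), and that of POU5F1 also without control replicate 1 (adjusted p = 0.108).

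**Figure D2:**
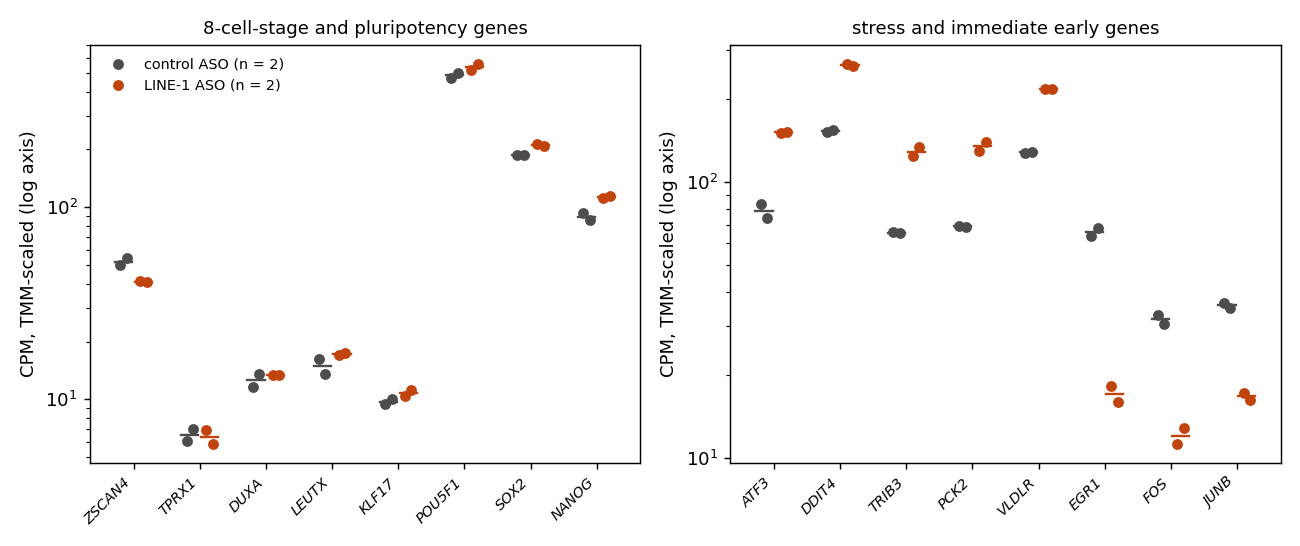
TMM-scaled CPM, relative to gene counts, in each of the 4 libraries for 8 marker genes of the 8-cell and pluripotent states and 8 response genes; each point is a library. ZSCAN4 lies at 52.2 in the control and 41.0 in the LINE-1 ASO libraries, EGR1 at 66.1 and 17.1, and TRIB3 at 65.5 and 129.

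The list of 8-cell genes had 11 of 51 members higher and 8 lower (9 and 8 when adjusted over the list alone), with a median of 0.07 that turned to -0.06 under upper-quartile factors (6 higher and 12 lower) and a mean of -0.00 (camera adjusted p = 0.393). ALPG, a germ cell alkaline phosphatase, rose by a log2 fold change of 0.51, the cyclin CCNA1 by 0.38 and the phosphate transporter SLC34A2 by 0.32. The homeobox gene ARGFX fell from 1.67 to 0.306 CPM, and DUX4, a many-copy gene whose single value is uncertain, chosen after its values were seen, from 5.69 to 2.84 CPM. With a length of 5047 bp, ARGFX lay near the density of the silent gene families in the control libraries (0.311 CPM per kb). Its fall is thus not told apart from theirs. Naive pluripotency genes had 12 of 30 higher and 6 lower, the same when adjusted over the list alone, with a median of 0.14, a mean of -0.14 and camera up without passing (adjusted p = 0.0741). It passed without control replicate 2 (adjusted p = 0.0146), without LINE-1 ASO replicate 1 (0.0394), without LINE-1 ASO replicate 2 (0.0460) and with the median background subtracted (0.0444). TFAP2C, a transcription factor of naive cells, rose 1.85-fold, CPT1A, which admits fatty acids to mitochondria, 1.83-fold and RAB15 1.40-fold, and DPPA2, which primes early embryonic genes, fell 3.16-fold, from 9.78 to 3.04 CPM.

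Primed pluripotency genes rose in 21 of 32 and fell in 2, the same when adjusted over the list alone (median 0.21, camera adjusted p = 5.68e-09; adjusted p = 0.183 with an estimated correlation). MAP1B, a microtubule protein of neurons, rose from 398 ± 2.71 to 844 ± 16.7 CPM (SD, n = 2; 2.12-fold), N-cadherin (CDH2) 1.75-fold, the Wnt receptor FZD7 1.72-fold and vimentin (VIM) 1.45-fold. OTX2 (-0.34) and DUSP6 (-0.28) fell. Among 10000 random lists matched on gene length and expression, the primed median lay at percentile 87.2, within their spread. Core pluripotency genes rose in 11 of 22 and fell in 2 (LIN28B, -0.21, and L1TD1, -0.19), the same when adjusted over the list alone, with a median of 0.13 that stood at -0.00 under upper-quartile factors (5 higher and 7 lower) (camera adjusted p = 0.0260; adjusted p = 0.296 with an estimated correlation). This call also ended with the median background subtracted (adjusted p = 0.536) and with a filter of 1 CPM in 2 libraries (adjusted p = 0.136). E-cadherin (CDH1) rose 1.43-fold, PODXL 1.33-fold and ZFP42 1.34-fold.

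Genes of the integrated stress response, which holds the transcription factor ATF4 and genes it acts on, rose in 30 of 35 and fell in 1, the same when adjusted over the list alone, with a median log2 fold change of 0.51 (camera adjusted p = 1.46e-27; adjusted p = 0.183 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, rose from 153 ± 2.56 to 266 ± 3.27 CPM (SD, n = 2; 1.74-fold; edgeR adjusted p = 1.67e-10). TRIB3, a pseudokinase that restrains ATF4, rose 1.98-fold, PCK2, the mitochondrial PEP carboxykinase, 1.95-fold, and VLDLR, a lipoprotein receptor, 1.70-fold. The member that fell was PPP1R15A (-0.31), which directs dephosphorylation of eIF2 alpha. The 4 that did not pass were DDIT3 (0.09), CEBPB (0.04), NUPR1 (0.34) and FGF21 (-0.32). ATF4 itself, chosen after its values were seen, rose by 0.10 (edgeR adjusted p = 0.0206). Heat shock and unfolded protein response genes rose in 16 of 28 and fell in 2 (HSPA1B, -0.23, and HSPA6, -0.58), the same when adjusted over the list alone (median 0.14, camera adjusted p = 5.49e-04; adjusted p = 0.258 with an estimated correlation). Under upper-quartile factors 9 were higher and 5 lower (median 0.01). With the median background subtracted 9 were higher and 3 lower (median 0.06) and this call ended (adjusted p = 0.0669), while with the far density it passed (adjusted p = 0.0496). The endoplasmic reticulum chaperones HSP90B1, PDIA4, HYOU1 and HSPA5 rose 1.41-fold, 1.40-fold, 1.40-fold and 1.31-fold.

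Immediate early genes, which respond within minutes to growth factors, fell in 14 of 23 and rose in 2, the same when adjusted over the list alone (median -0.44, camera adjusted p = 9.45e-04; adjusted p = 0.258 with an estimated correlation). EGR1 fell 3.92-fold, from 66.1 ± 3.11 to 17.1 ± 1.53 CPM (SD, n = 2; edgeR adjusted p = 1.26e-11), FOS 2.61-fold and JUNB 2.14-fold. ATF3, which the integrated stress response list also holds, rose 1.93-fold, and BTG1 rose by a log2 fold change of 0.33. Interferon-stimulated genes rose in 7 of 30 and fell in 9 (7 and 8 when adjusted over the list alone), with a median of -0.03 that turned to 0.04 with DESeq2 size factors and stood at -0.16 under upper-quartile factors, with 4 higher and 12 lower (camera adjusted p = 0.880). IFIT2, which binds viral RNA, fell from 8.29 ± 0.968 to 1.26 ± 0.00738 CPM (6.59-fold), IFIT1 2.95-fold and IFI35 2.78-fold, while PARP14 rose 1.32-fold. Of p53 target genes 8 of 30 rose and 11 fell, the same when adjusted over the list alone, with a median of -0.02 that turned to 0.07 with DESeq2 size factors and stood at -0.15 under upper-quartile factors, with 3 higher and 15 lower (camera adjusted p = 0.848). The cell cycle inhibitor CDKN1A fell 1.62-fold and MDM2, the ligase for p53, 1.44-fold, while TP53INP1 rose 1.98-fold and SESN2 1.37-fold.

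G2/M genes rose in 28 of 32 and fell in 1 (30 and 1 when adjusted over the list alone), with a median of 0.32 (camera adjusted p = 2.37e-09; adjusted p = 0.183 with an estimated correlation). MKI67, a proliferation marker, rose from 95.6 ± 3.48 to 153 ± 1.55 CPM (SD, n = 2; 1.59-fold), the mitotic kinase PLK1 1.58-fold, the kinetochore motor CENPE 1.52-fold and the spindle factor TPX2 1.40-fold, and KIF20B fell (-0.12). S phase genes rose in 11 of 30 and fell in 4 (CCNE2, GINS2, PCNA and UNG), the same when adjusted over the list alone, with a median of 0.07 that turned to -0.06 under upper-quartile factors (3 higher and 7 lower) (camera adjusted p = 0.182). SLBP, which binds histone mRNA, rose by a log2 fold change of 0.48, CLSPN by 0.39 and CDCA7 by 0.32, and cyclin E2 (CCNE2) fell 1.55-fold. Glycolysis genes rose in 17 of 24 and fell in 1, ALDOC (18 and 1 when adjusted over the list alone), with a median of 0.24 (camera adjusted p = 8.31e-06; adjusted p = 0.258 with an estimated correlation). Among random lists matched on gene length and expression, this median lay at percentile 88.3, within their spread. The G2/M median lay at percentile 99.97 of such lists, and the immediate early and histone medians at percentile 0. The enzymes ENO2, PFKP and PKM rose 1.41-fold, 1.41-fold and 1.32-fold and the glucose transporter SLC2A1 1.27-fold.

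**Figure D3:**
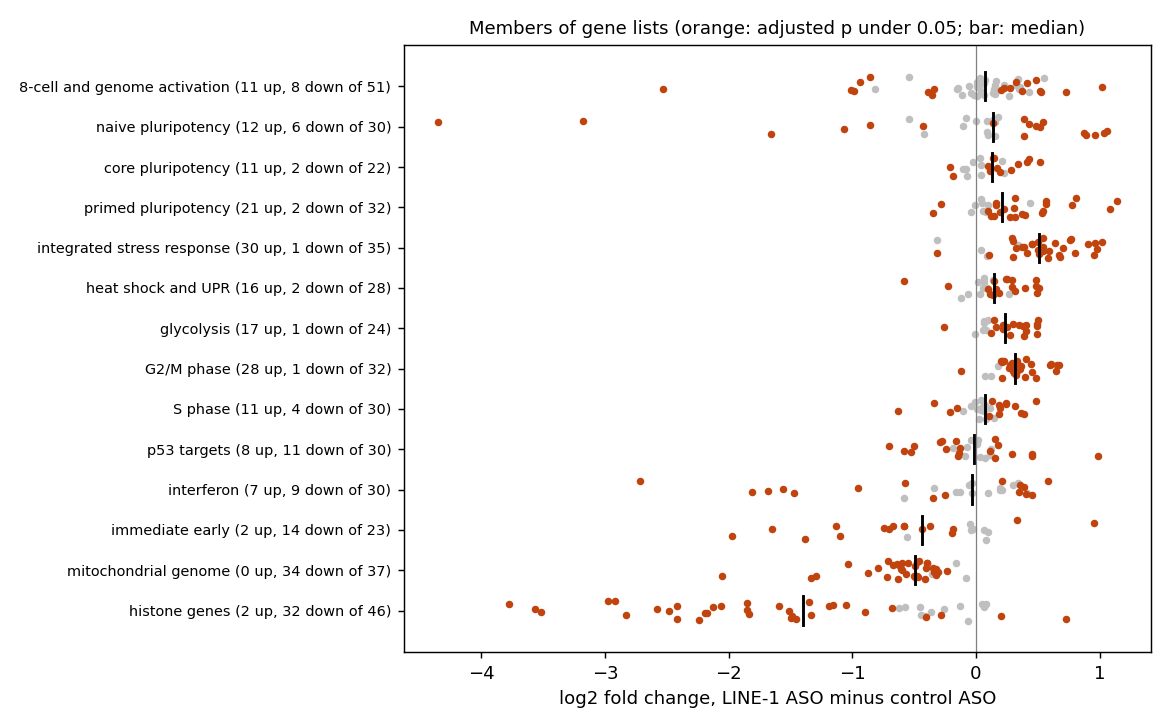
Log2 fold changes, LINE-1 ASO minus control ASO, of the tested members of 14 gene lists; each point is a gene, orange where its edgeR adjusted p is under 0.05, and each bar is the list's median. The medians lie at 0.51 for integrated stress response genes, 0.32 for G2/M genes and -1.40 for histone genes, and at 0.07 for 8-cell genes, which turns to -0.06 under upper-quartile factors; the medians of core pluripotency, S phase, p53 and interferon genes also change sign between scalings.

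Histone genes fell in 32 of 46, the same when adjusted over the list alone (median -1.40, camera adjusted p = 1.39e-06; adjusted p = 0.231 with an estimated correlation). H2BC21 fell from 19.7 ± 1.07 to 1.68 ± 0.0545 CPM (SD, n = 2; 11.8-fold), H4C5 13.7-fold and H2BC15 7.13-fold; histone genes are close copies, so their single values are uncertain. Transcripts of the mitochondrial genome fell in 34 of 37 (35 when adjusted over the list alone) and none rose (median -0.50, camera adjusted p = 9.64e-19; adjusted p = 0.296 with an estimated correlation). The ribosomal RNAs MT-RNR1 and MT-RNR2 fell 2.45-fold and 1.65-fold, and the transfer RNAs MT-TF and MT-TV 4.15-fold and 2.53-fold. The mitochondrial share of gene counts was 6.81% and 6.44% in the control against 4.79% and 4.34% in the LINE-1 ASO libraries. ZNF zinc finger genes, many of which repress retroelements, rose in 82 of 513 and fell in 226 (83 and 229 when adjusted over the list alone; median -0.17, camera adjusted p = 0.0103; adjusted p = 0.468 with an estimated correlation). Under upper-quartile factors 35 were higher and 305 lower (median -0.30). ZNF560 fell from 21.0 to 1.54 CPM (13.6-fold), ZNF546 4.03-fold and ZNF165 2.61-fold, and ZNF75D rose 2.12-fold.

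Among factors that restrict or silence LINE-1, 10 of 38 rose and 5 fell, the same when adjusted over the list alone, with a median of 0.08 that turned to -0.05 under upper-quartile factors (4 higher and 14 lower) (camera adjusted p = 0.288). ZC3HAV1 rose 1.33-fold and the RNA editor ADAR 1.23-fold. MPHOSPH8 of the HUSH complex fell 1.37-fold, ZCCHC8 of the nuclear exosome targeting complex 1.36-fold, and HELLS (-0.28), PIWIL2 (-1.60) and SETDB1 (-0.14) fell too. Ribosomal protein genes rose in 17 of 84 and fell in 12 (17 and 10 when adjusted over the list alone), with a median of 0.04 that turned to -0.09 under upper-quartile factors (2 higher and 35 lower), a mean of -0.02 and camera up without passing (adjusted p = 0.361). Without LINE-1 ASO replicate 2 it passed (adjusted p = 8.24e-03). RPL10A and RPL3 rose 1.23-fold and 1.17-fold, and RPS26 and RPS27L, the latter a p53 target, fell 1.46-fold and 1.42-fold. Ribosome biogenesis genes rose in 15 of 42 and fell in 5 (15 and 4 when adjusted over the list alone), with a median of 0.06 that turned to -0.07 under upper-quartile factors (3 higher and 12 lower) (camera adjusted p = 0.117, and 0.0344 and 0.0342 without LINE-1 ASO replicate 1 and 2). BOP1, TAF1D, MYBBP1A and NOP56 rose by 0.34, 0.30, 0.25 and 0.19 on the log2 scale, the call of NOP56 ending under upper-quartile factors. NAT10, NOP2, NPM1, RRN3 and WDR12 fell.

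Splicing factor genes rose in 14 of 31 and fell in 7 (15 and 7 when adjusted over the list alone), with a median of 0.08 that turned to -0.05 under upper-quartile factors (7 higher and 14 lower) (camera adjusted p = 0.0854, and 0.0198 and 0.0103 without LINE-1 ASO replicate 1 and 2). SRSF7, SRSF3 and SNRNP70, a protein of the U1 particle, rose 1.38-fold, 1.33-fold and 1.26-fold, and the kinase CLK1 fell 1.39-fold. Nuclear and small nucleolar RNA host transcripts rose in 8 of 38 and fell in 16, the same when adjusted over the list alone (median -0.13, camera adjusted p = 0.288). SNHG5 fell from 123 ± 3.49 to 48.4 ± 1.59 CPM (SD, n = 2; 2.55-fold), SNHG26 2.64-fold and MALAT1, an abundant nuclear RNA, 1.94-fold, while SNHG32 rose 1.64-fold. Nuclear respiratory chain genes rose in 20 of 93 and fell in 14 (17 and 12 when adjusted over the list alone), with a median of 0.03 that turned to -0.10 under upper-quartile factors (4 higher and 34 lower) and a mean of -0.01 (camera adjusted p = 0.361). UQCRC1, NDUFV1 and ATP5F1A rose 1.33-fold, 1.31-fold and 1.27-fold. Cholesterol synthesis genes rose in 5 of 25 and fell in 7, the same when adjusted over the list alone, with a median of 0.00 that turned to -0.13 under upper-quartile factors (2 higher and 13 lower) and a mean of -0.01 (camera adjusted p = 0.880). SREBF2, the pathway's transcription factor, rose 1.26-fold, SC5D 1.23-fold, and FDPS, LSS and STARD4 by 0.18, 0.15 and 0.15 on the log2 scale. IDI1 fell 1.34-fold and HSD17B7 1.26-fold.

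Of the markers of other cell types, mesenchymal genes rose in 12 of 17 and fell in 1, the same when adjusted over the list alone (median 0.38, camera adjusted p = 5.49e-04; adjusted p = 0.296 with an estimated correlation). The collagens COL5A1 and COL1A2 rose 2.12-fold and 1.67-fold, and the actin-binding protein TAGLN rose from 447 to 582 CPM, while COL3A1 fell from 4.03 to 0.137 CPM. Trophectoderm markers rose in 6 of 18 and fell in 7 (7 and 7 when adjusted over the list alone), with a median of -0.05 that turned to 0.02 with DESeq2 size factors, a mean of -0.52 and camera up without passing (adjusted p = 0.848). SLC7A2 rose 1.46-fold, TEAD3 1.35-fold and keratin KRT19 1.20-fold, and TFAP2A fell from 2.25 to 0.336 CPM. With a length of 8218 bp, TFAP2A was no denser in the control libraries than the silent gene families (0.311 CPM per kb). Its fall is thus not told apart from theirs. Endoderm markers rose in 3 of 12 (CER1 1.51-fold, LAMA1 1.47-fold and GATA4) and fell in 4 (FRZB from 4.90 to 1.63 CPM, TTR from 0.985 to 0.0420 CPM, CXCR4 and NID2), the same when adjusted over the list alone. The endoderm median of -0.02 turned to 0.09 with DESeq2 size factors, the mean was -0.32, and camera was up without passing (adjusted p = 0.573).

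Mesoderm markers rose in 4 of 15 and fell in 6, the same when adjusted over the list alone, with a median of -0.41, a mean of -0.55 and camera up without passing (adjusted p = 0.848). The VEGF receptor KDR rose 1.99-fold, from 87.6 ± 2.03 to 174 ± 0.0839 CPM (SD, n = 2), NKX1-2 rose 1.28-fold, and BMP4 and SP5 by 0.31 and 1.03 on the log2 scale. FOXF1 fell from 2.37 to 0.158 CPM and MSGN1 from 1.02 to 0.105 CPM. Neuroectoderm markers rose in 5 of 13 (NES 1.45-fold, SOX3 1.41-fold, TUBB3 1.28-fold, DCX and STMN2) and fell in 4 (ELAVL4, from 1.62 to 0.0629 CPM, NEUROG2, PAX6 and SOX1), the same when adjusted over the list alone. The neuroectoderm median of -0.00 turned to 0.07 with DESeq2 size factors, the mean was -0.43, and camera was up without passing (adjusted p = 0.544). Amnion markers rose in 2 of 7 (BAMBI, 1.42-fold, and CLDN10) and fell in 1 (HEY1), or 1 and 0 when adjusted over the list alone, with a median of 0.12 that turned to -0.02 under upper-quartile factors (camera adjusted p = 0.544). The calls of HEY1 and CLDN10 ended with DESeq2, with the background subtracted and without control replicate 2 (adjusted p = 0.174 and 0.355). That of HEY1 ended also without control replicate 1 (adjusted p = 0.108) and without LINE-1 ASO replicate 1 (0.185), and that of CLDN10 without LINE-1 ASO replicate 2 (0.0595). IGFBP3 had 0.12 without passing (adjusted p = 0.272). The lineage markers that fell furthest (COL3A1, FOXF1, TTR and ELAVL4) were at 4.03 CPM or less in the control libraries. With the median background subtracted, COL3A1, FOXF1 and TTR still fell, by log2 fold changes of -4.37, -3.65 and -3.61 (edgeR adjusted p = 1.31e-06, 1.19e-05 and 1.03e-03), and ELAVL4 gave no value. A silent gene denser than the median can still fall after this subtraction, as OR5AU1 did (-5.74). These values therefore do not tell a fall of the markers apart from the background.

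With the median background subtracted, the higher and lower members numbered 5 and 6 of core pluripotency, 3 and 19 of ribosomal protein, 6 and 8 of ribosome biogenesis and 7 and 24 of nuclear respiratory chain genes. The medians of mesoderm, endoderm, neuroectoderm, trophectoderm and interferon genes then stood at -0.16, 0.36, 0.26, 0.09 and 0.22.

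Of the gene lists, 11 of 28 passed the threshold by camera with the preset correlation. None passed with an estimated correlation, where 4 lists had an unadjusted p under 0.05, and 18 passed by fry. The replicates of a group agreed more closely than the groups did (biological coefficient of variation 3.2%), and with 2 libraries per ASO that are not named as separate cultures a difference between cultures is not separated from an effect of the ASO.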

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

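The fits on genes at least 10 times the background, on protein-coding genes and on background-subtracted counts were chosen after the data were seen; all other settings were planned. Up to 15 planned settings were run for the 157 genes and repeats named by rule (those filtered out in a setting have no value). In these, 2280 values kept their side of the threshold, 42 no longer passed, 8 newly passed and 1 reversed. Over the subtractions, 282, 13, 2 and 3 did so. A change of direction was counted as a reversal only where a value passed. DUXA, which went from 0.071 to -0.008 and -0.003 under the subtractions without passing, is thus not counted. The reversals were LTR6A (-0.018 under upper-quartile factors), L1PA6 (0.047 with the median background subtracted), and L1PA2 (0.538) and L1PA3 (0.359) with the density far from expressed genes subtracted, which removed 79.6% and 79.5% of their control counts; the cause was not tested. The LINE-1 total stayed lower in every setting fitted, from -1.87 to -1.52 in the planned ones, at -0.68 and -0.89 after the subtractions of the median and far densities (the pooled density of all silent genes exceeds the LINE-1 counts and was not fitted) and from -1.73 to -1.70 when a library was left out.

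DESeq2 called 10488 genes, 4972 of them lower; the cause was not tested. Upper-quartile factors gave 4312 genes higher, by construction of a scaling that moves the gene median by -0.13. A log2 fold change of at least 1 left 6128 genes, 264 higher and 5864 lower, and 0 repeats higher. Genes at least 10 times the background gave 7831 changed and 2144 lower, and protein-coding genes 9731 and 3676; fewer genes were tested, but the cause of the larger loss among lower genes was not tested. With a mean TPM of at least 1, 36 repeats of 163 tested changed, 35 lower and 1 higher, against 1096 of 1149 by the same test without this filter; the cause was not tested. The count of repeats higher, 4, became 1 under upper-quartile factors, 9 with no filter, 2 with at least 1 CPM in 2 libraries, 1 on log2(TPM + 1) and 1 on log2(TPM + 0.1). It became 47 and 27 with the median and the far density subtracted, which take counts only or almost only from the control libraries. The cause was not tested. Leaving out a library in turn gave 1 to 5 repeats higher, the 1 without control replicate 2, and 11867 to 17798 genes changed, 11 to 15 gene lists and 4 to 7 repeat lists. The lone library left in a group is then assumed to vary like those of the other group.

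Camera with an estimated correlation called 0 gene lists (lowest adjusted p = 0.183, 4 at an unadjusted p under 0.05) and 0 repeat lists (0.818, none). Fry called 18 and 15. In simulated data neither found a single list raised by a small fold, but the simulated genes varied independently. In these libraries the estimated correlation was 0.327 for mitochondrial genes and 0.546 for L1M. The simulation therefore does not decide between the settings. With the far density subtracted, 2 of 11 repeat lists that could be tested passed; the cause was not tested. With the replicate number as a replicate block, 16542 genes, 1133 repeats, 11 gene lists and 6 repeat lists passed, and the LINE-1 total stood at -1.735. The replicate numbers share a label alone: over 16122 genes the replicate differences of the groups had r = -0.019 and rho = 0.032 across genes, which are not independent replicates. Replicates of a group differed by more than counting noise (chi-square per degree of freedom 1.33 over 27919 genes in the control and 2.55 over 23895 in the LINE-1 ASO group). With the median density subtracted, 164 repeats and 709 genes lost over 80% of their control counts and gave no value.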

Other observations

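Of the tests below, those of the background and of the ASO's own effect on repeats, of the background for small nuclear RNAs, of S phase and of separate cultures were chosen after the results were seen. Several noncoding gene types had lower medians than coding genes, beside a loss of 0.230 CPM per kb in silent gene families, while microRNA genes had a higher one (0.15; 63 of 327 rose and 40 fell). Of 1811 long intergenic noncoding RNA genes tested, 1166 fell and 96 rose (median log2 fold change -1.11), and of 285 genes annotated inside introns on the same strand, 183 fell and 13 rose (-1.18). Of 2714 antisense genes 1072 fell and 350 rose (-0.27), with the strand of the reads not stated. Of 16390 protein-coding genes 3666 fell and 6046 rose (median 0.09, smaller than the shift of -0.13 that upper-quartile factors give). Small nuclear RNA genes, the RNA parts of the spliceosome, fell in 56 of 79 and rose in 1, with a median of -2.64; many are near-identical copies, so their single values are uncertain.

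Among other short RNAs without a poly(A) tail, chosen as a list before their values were seen, 3 of 6 tested fell. RMRP, the RNA of a ribosomal RNA processing enzyme, fell from 0.777 to 0.0844 CPM, a few counts per library, RPPH1, the RNA of ribonuclease P, from 3.09 to 0.422 CPM, and RN7SK, which holds back transcription elongation, from 3.71 to 1.65 CPM (edgeR adjusted p = 2.03e-04, 1.10e-06 and 2.57e-04, in both libraries of each group). The signal recognition particle RNAs RN7SL1, RN7SL2 and RN7SL3 had log2 fold changes of -0.23, -0.21 and -0.34 without passing.

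The repeats fell together, inside LINE-1 and outside it. The median log2 fold change of -1.507 in repeats outside LINE-1 argues against an effect on LINE-1 alone as the source of the whole fall. It does not decide whether the ASO acted on LINE-1 alone, since a background in the control libraries would lower other repeats too. A broad background of reads in the control libraries, such as genomic DNA, is a candidate explanation for much of the fall of LINE-1: LINE-1 lost 0.868 times as many CPM per kb as the silent gene families, though 1.42 times as many as the silent genes over 100 kb from expressed genes. It leaves open why satellites lost only 0.00248 CPM per kb and why single silent families ranged from 0.0779 to 0.776, with the rule for multiply matching reads not given. Unspliced RNA of expressed genes may add to it. The silent genes far from expressed genes lost 0.140 CPM per kb, against 0.376 in those within 10 kb of one. Far genes thus lost less, 0.373 times as much (95% bootstrap interval over genes 0.240 to 0.621). This interval crosses the cutoff set in advance for this explanation, so the explanation stays undecided. Whether the ASO lowered the youngest LINE-1 RNA on top of the shared fall cannot be told apart from the background here, because the median density takes a median of 82.2% of the control counts of L1HS and L1PA2 to L1PA4.

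Small nuclear RNAs and histone transcripts, neither of which ends in a poly(A) tail, fell together. The same background is argued against for 14 small nuclear RNA genes picked by name, which together lost 266 times as many CPM per kb as the silent families. This value is pooled, so abundant members may carry it. Fewer cells in S phase are argued against for the histones. The S phase list had a median of 0.07 (95% bootstrap interval 0.04 to 0.14), or -0.06 (-0.09 to 0.01) under upper-quartile factors. Each lies far from the histone median of -1.40, though 4 of the 30 S phase genes fell and 11 rose. These intervals resample the genes of the list, not the libraries, so they do not cover variation between cultures. A lower yield of RNA without a poly(A) tail in the LINE-1 ASO libraries could account for the fall of small nuclear RNAs and of histone transcripts. The other such RNAs had a median of -0.753, but with 6 tested, 3 of them past the threshold, this stays open. A true fall of these RNAs after the LINE-1 ASO stays open too, as untested.

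The integrated stress response genes rose together. With the median background subtracted, the list's median was 0.444, against 0.51 before. Extra reads in the control libraries would make a gene look lower in the LINE-1 ASO group, not higher. Apart from a change of scaling, subtracting them was not able to remove this rise. The subtraction is therefore no test of the background as their cause. Gene length and expression level are argued against by 10000 random lists matched on both, among which their median lies at percentile 100, with the 99th percentile at 0.25. A difference between cultures cannot be told apart from an effect of the ASO, because no label names the cultures and the biological coefficient of variation between libraries of a group is 3.2%. An effect of LINE-1 loss, or of this oligonucleotide whatever its target, may also raise these genes, and the design, with 1 ASO against LINE-1, does not part them.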
